A study of Homo sapiens with 6 samples.

How the data were processed

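Transcripts were measured by RNA-seq in 6 libraries of HEKa, 3 with DMSO and 3 with PY-60 for 24 h, grouped by the treatment in the labels. Per the submitters' processing notes kallisto, which assigns reads to transcripts by pseudoalignment, and the build GRCh37.p13 were used; the kallisto version is not given in the sources used here. The authors deposited 1 gene-level table under a name that announces raw counts, but its values are not whole numbers and behave as TPM, that is, reads scaled by transcript length and by the library total. They were therefore treated as deposited TPM. The table has 21695 rows, of which 4842 are 0 in every library, and 20917 of its row names match a current gene symbol. TPM keeps no read counts, so no counting interval was computed, and steps between low values gave only the relative depth of the libraries. The authors also deposited a comparison of the groups. Its p-values equal those of a two-sided unequal-variance test on linear TPM without adjustment for all 16853 genes that have one (within 1e-10), and its fold is the ratio of the group means.

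The design fixed before the data were examined foresaw a count test and, for normalized values, limma. limma 3.58.1 in R 4.3.3 with statmod 1.5.0 was fitted to log2(TPM + 1) by treatment, without a replicate block, with a mean-variance trend and robust moderation. Genes with a mean of at least 1 TPM over the 6 libraries were tested (10119 genes); this filter was set after the unit was known. Genes passed at a Benjamini-Hochberg adjusted p below 0.05, two-sided. On simulated data for this comparison, run on 10119 genes, 0% of 1.25-fold, 40% of 1.5-fold, 80% of 2-fold and 96% of 4-fold changes were recovered, with 3 false calls among 111. Only 50 genes per fold were changed, far fewer than were called in the data. The adjusted threshold was therefore stricter in the simulation, and these rates may understate recovery in the real comparison. The simulated folds were of TPM + 1. For genes of low TPM an equal fold of TPM is a smaller change on that scale, so the rates may overstate its recovery.

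Fixed gene lists, 28 in all, were tested with camera (inter-gene correlation 0.01) over the 26 lists with at least 3 tested genes, adjusted over those lists, then with an estimated correlation and with fry. All camera calls were lost with an estimated correlation. List medians were set against 10000 random lists drawn from 20 classes of mean expression. The mitochondrially encoded and nuclear-retained lists had 0 genes in the table and were not analysed here. Lists of other genes (histone deacetylase inhibitor response, neuronal, germline and cancer-testis, abundant fibroblast transcripts, tubulins) were added after the fixed lists were seen.

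Named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest log2 fold changes and the 5 smallest p-values per direction among genes past the threshold, with at least 5 TPM in the higher group and separated libraries. It added 15 genes by name, up to 4 called members per list, and every called YAP/TAZ target. YAP1, KRT5, KRT1 and IVL were not analysed here, and 2 genes that the rule names are not reported here. IL1A, F3 and others that several parts of the rule name count under each.

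The alternatives were other scalings, filters, pseudocounts, variance models, a replicate block, a stricter threshold, leaving out each library, and only genes typed protein-coding. The annotation at hand belongs to another build, so it supplied only gene types and symbols and no coordinates are given. The labels call the libraries biological replicates but do not say whether they came from separate donors or cultures, so p-values measure the spread between these libraries. No sequencing batch is stated. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.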

Results

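Transcript abundance was measured by RNA-seq of total RNA from HEKa, primary human epidermal keratinocytes, the main cells of the outer skin layer. They were exposed for 24 h to PY-60, which the series title presents as a pharmacological activator of YAP, or to DMSO, the solvent control. YAP and its paralog TAZ are transcriptional coactivators restrained by the Hippo kinases. There were 3 DMSO and 3 PY-60 libraries, each called a biological replicate. The labels state about 58000000 paired-end reads per library. The deposited TPM, a unit of transcript abundance scaled by length and library total, of the rows held summed to between 520327 and 546392 per library; the remainder of each library's TPM was not analysed here. Between 8774 and 8954 rows reached 1 TPM in a DMSO library, and between 10565 and 10639 did so in a PY-60 library. Values below are mean TPM ± SD over 3 libraries per group. Log2 fold changes are PY-60 minus DMSO on the log2(TPM + 1) scale, which understates changes of low genes, and adjusted p values are from limma with Benjamini-Hochberg adjustment.

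The comparison asked how PY-60 altered the transcriptome of these keratinocytes. ANKRD1, a classical YAP target, rose from 2.29 ± 0.60 to 114 ± 3.31 TPM, and IGFBP3, which binds insulin-like growth factors, rose from 3.67 ± 0.42 to 74.1 ± 0.67 TPM. Most interferon-response and mesenchymal genes rose, and genes with a mean of 1 to 5 TPM contained 1816 rises and 121 falls. Terminal differentiation genes, mitotic genes and genes of ribosome biogenesis contained falls and no rises. Among single abundant transcripts, tissue factor (F3), the cytokine gene IL1A and the tubulin genes TUBA1C and TUBA4A fell to between 0.161 and 0.26 of their DMSO level.

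Of 10119 genes tested, 4671 rose and 1513 fell. At least 2-fold changes numbered 2252 upward and 114 downward. The excess of rises among all calls depended on the scaling, but an excess among at least 2-fold changes remained. These numbered 1642 upward and 367 downward with median-of-ratios scaling, and 1652 and 361 with upper quartile scaling. On TPM the median log2 fold change over all genes was 0.27 and 75.5% of the calls were rises. With median-of-ratios scaling this median moved to -0.05, with 3237 rises and 3434 falls (48.5% rises), and with upper quartile scaling it moved to -0.04, with 3267 rises and 3399 falls (49% rises). A change of about 0.3 on the log2 scale therefore had a direction that rested on the scaling. All PY-60 libraries lay above all DMSO libraries for 4927 genes (48.7%) and below them for 1740 (17.2%), where chance gives 10% in both directions together. The first principal component held 89.9% of the variance. The authors' deposited table had 5155 genes marked higher and 1290 lower at an unadjusted p below 0.05, of 16853 genes with a p; 4060 of the 4671 rises and 1158 of the 1513 falls carried the same mark, and 0 genes were marked in the opposite direction.

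**Figure D1:**
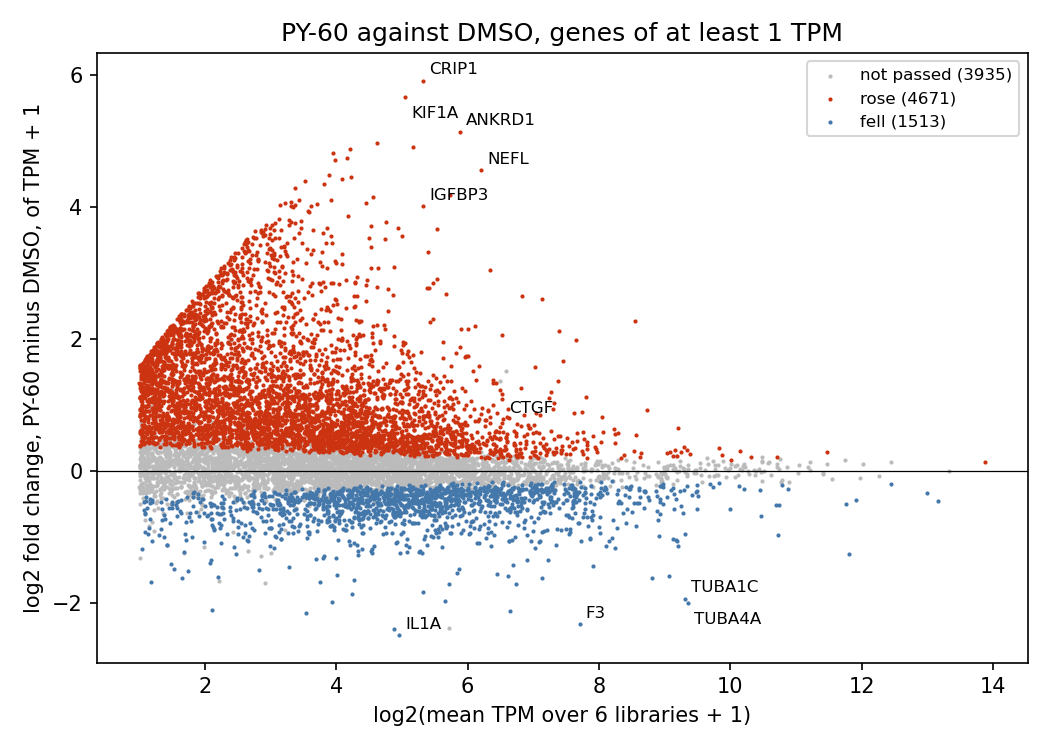
Log2 fold change of TPM + 1 (PY-60 minus DMSO, y axis) against log2(mean TPM over 6 libraries + 1) (x axis), 1 point per tested gene. Red points are the 4671 genes that rose, blue points the 1513 that fell and grey points those that did not pass the test; the highest red points lie at low to middle abundance, and with median-of-ratios scaling 3237 genes rose and 3434 fell.

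The 10 genes with the highest log2 fold change by the fixed rule were CRIP1, KIF1A, ANKRD1, RTN4RL2, TPPP3, IGF2, PPP1R1A, WNT11, THY1 and NEFL. CRIP1, a small LIM-domain protein, went from 0.33 ± 0.32 to 77.3 ± 5.28 TPM (log2 fold change 5.91, SE 0.17, adjusted p = 6.92e-09). KIF1A, an axonal kinesin, went from 0.28 ± 0.21 to 63.5 ± 5.19 TPM, and NEFL, the neurofilament light chain, from 5.08 ± 1.07 to 140 ± 2.39 TPM. RTN4RL2, a Nogo receptor family member, reached 46.8 ± 2.00 TPM and the tubulin-binding TPPP3 68.7 ± 6.02 TPM, from 0.53 ± 0.17 and 1.40 ± 0.74 TPM. The growth factor IGF2 went from 0.22 ± 0.03 to 34.9 ± 1.88 TPM, and the ligand gene WNT11 from 0.30 ± 0.15 to 33.5 ± 2.75 TPM. PPP1R1A, a protein phosphatase inhibitor listed at 0 in 2 DMSO libraries, reached 28.8 ± 4.68 TPM. THY1, a surface glycoprotein of fibroblasts and neurons, went from 0.16 ± 0.13 to 29.5 ± 3.33 TPM.

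The 10 genes with the lowest log2 fold change were IL1A, PLA2G4B, F3, DHRS9, PAQR7, TRIM31, TUBA4A, SDR9C7, RNF39 and TUBA1C. IL1A, an alarmin cytokine of keratinocytes, fell from 51.6 ± 8.16 to 8.30 ± 0.73 TPM (log2 fold change -2.49, SE 0.13, adjusted p = 8.69e-08). F3 fell from 347 ± 41.7 to 68.2 ± 3.06 TPM and PAQR7, a membrane progestin receptor, from 162 ± 7.78 to 36.1 ± 1.76 TPM. The short-chain dehydrogenase genes DHRS9 and SDR9C7, both expressed in differentiating epidermis, fell from 18 ± 1.65 to 3.26 ± 0.49 TPM and from 23.5 ± 2.07 to 5.17 ± 0.38 TPM. TUBA1C fell from 1008 ± 9.77 to 262 ± 9.48 TPM, TUBA4A from 1050 ± 58.4 to 260 ± 2.44 TPM and TUBB4B from 808 ± 14.6 to 266 ± 10.2 TPM. Tubulin genes have near-identical copies, and PLA2G4B overlaps a read-through transcript, so the counting could split their reads and these levels are uncertain. The ubiquitin ligase genes TRIM31 and RNF39 fell from 6.05 ± 1.94 to 0.59 ± 0.04 TPM and from 79.4 ± 13.6 to 19.2 ± 0.52 TPM.

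YAP/TAZ targets moved both ways. Of 17 tested, 8 rose, 5 fell and 4 did not pass, with the same counts adjusted over the list alone. The rises were ANKRD1 (log2 fold change 5.14, SE 0.13), IGFBP3 (4.01, SE 0.10), TGFB2 (1.29, SE 0.21), CCDC80 (1.04, SE 0.11), ARHGEF17 (1.03, SE 0.22), LATS2 (0.84, SE 0.12), AXL (0.83, SE 0.12) and CTGF (0.78, SE 0.07), and each remained a rise with median-of-ratios scaling. CTGF, also named CCN2 and a widely used YAP readout, rose from 67.6 ± 3.23 to 116 ± 2.50 TPM. CYR61, also named CCN1 and the companion readout, was 122 ± 17.3 and 138 ± 8.90 TPM (adjusted p = 0.125), and its adjusted p was 0.00771 without DMSO replicate 1. The falls were F3 (-2.32, SE 0.09), NUAK2 (-1.03, SE 0.12), AMOTL2 (-0.91, SE 0.08), FJX1 (-0.30, SE 0.10) and GADD45A (-0.30, SE 0.08). The fall of FJX1 did not pass without DMSO replicate 2 (adjusted p = 0.0572), PY-60 replicate 1 (0.075) or PY-60 replicate 2 (0.0858).

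As a list, the YAP/TAZ targets did not stand apart from other genes by a shift in a shared direction. Camera and the list median look only for such a shift, which a list with both rises and falls need not show. Whether the targets changed more than other genes regardless of direction was not tested. Camera gave the direction down with adjusted p = 0.709, and adjusted p = 0.905 with an estimated correlation. The list median was 0.19 and its mean 0.59, both positive. Camera compares a list with the other genes, so its direction down does not mean a change below 0. The median of all genes was 0.27. The median lay at percentile 79.9 of 10000 random lists matched on mean expression. The directional rotation test fry, which asks whether the list moves on balance against 0, gave up with adjusted p = 0.00281, but it also gave up for 10 other fixed lists that did not pass camera, so this was not particular to YAP/TAZ. With median-of-ratios scaling 8 targets rose, 8 fell and the list median was -0.15.

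**Figure D2:**
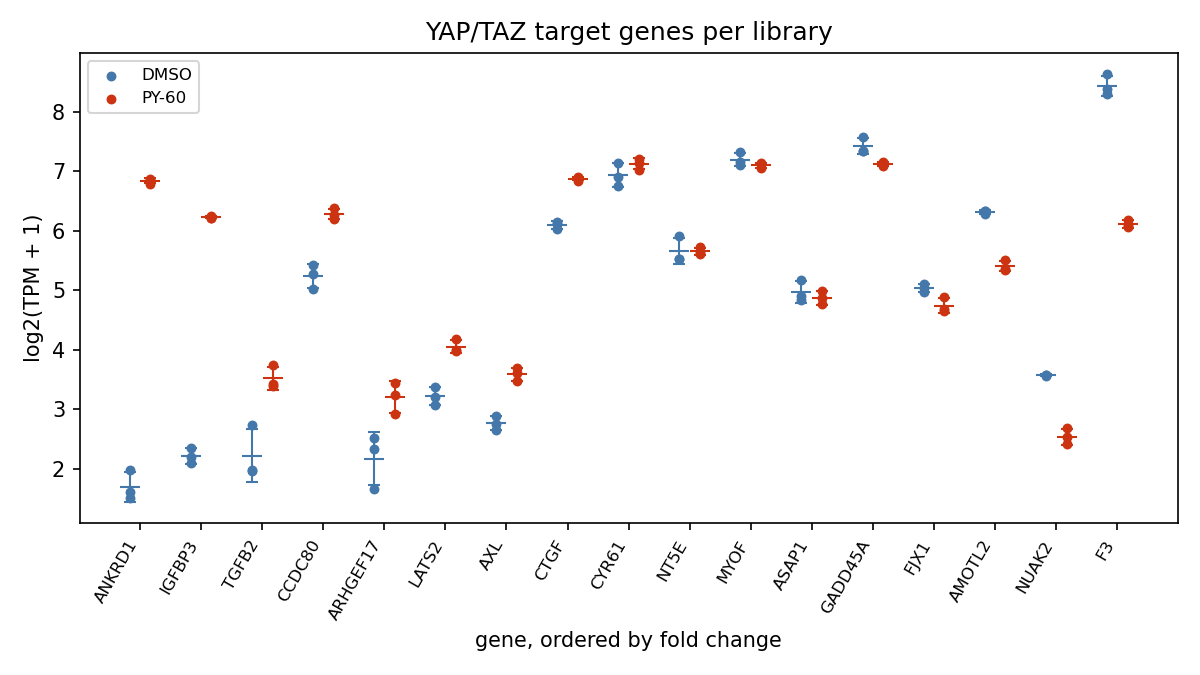
Log2(TPM + 1) (y axis) of the 17 tested YAP/TAZ targets (x axis, ordered by fold change), with 1 point per library in blue for DMSO and red for PY-60, and horizontal bars with whiskers for the mean and SD of 3 libraries. ANKRD1 and IGFBP3 rose by 5.14 and 4.01, F3 fell by 2.32, and CYR61 overlapped between groups.

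Hippo pathway genes changed in both directions. Of 18 tested, 7 rose, 3 fell and 8 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.971). The TEAD factors are the DNA-binding partners of YAP. TEAD2 rose from 1.66 ± 0.53 to 15.4 ± 0.80 TPM (log2 fold change 2.64) and TEAD4 from 3.47 ± 0.48 to 6.81 ± 1.18 TPM (0.80). MOB1B, a cofactor of the LATS kinases, rose by 1.09. AJUBA, a LIM protein that restrains LATS, fell from 58.0 ± 7.92 to 30.4 ± 3.50 TPM. ANXA2, encoding a membrane-associated annexin, went from 5950 ± 331 to 5180 ± 138 TPM (-0.20, adjusted p = 0.00971), which did not pass without a mean-variance trend (adjusted p = 0.0894). TEAD1 was 7.67 ± 1.85 and 9.40 ± 0.53 TPM (adjusted p = 0.144, or 0.016 without DMSO replicate 1), and WWTR1, which encodes TAZ, was 16.3 ± 1.09 and 19.7 ± 1.84 TPM (adjusted p = 0.0633, or 0.0405 without PY-60 replicate 3 and 0.0476 rescaled to the total of the rows held). With median-of-ratios scaling 5 members rose, 5 fell and the list median moved from 0.25 to -0.08.

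Epidermal terminal differentiation genes contained 8 falls, 0 rises and 13 that did not pass among 21 tested, with the same counts adjusted over the list alone. CNFN, a cornified envelope component, fell from 680 ± 104 to 217 ± 23.5 TPM. TGM1, the envelope cross-linking transglutaminase, fell from 166 ± 18 to 87.8 ± 7.14 TPM, the desmosomal cadherin DSG1 from 292 ± 22.9 to 162 ± 6.32 TPM, and the transcription factor gene GRHL3 from 57.9 ± 3.10 to 28.5 ± 1.98 TPM. KRT10, an early differentiation keratin, was 164 ± 20.2 and 153 ± 20.3 TPM (adjusted p = 0.447) and passed as a fall only with median-of-ratios (adjusted p = 0.00441) or upper quartile scaling (0.00425). Camera gave down with adjusted p = 1.81e-05, which did not hold with an estimated correlation (adjusted p = 0.394 with an estimated correlation). The list median of -0.23 lay at percentile 1.95 of matched random lists. With median-of-ratios and with upper quartile scaling 17 genes fell and 0 rose.

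Basal keratinocyte genes went both ways, with 6 rises, 4 falls and 4 that did not pass among 14 tested, the same adjusted over the list alone (camera adjusted p = 0.496). TP63, the master regulator of basal cells, rose from 25.8 ± 1.77 to 42.8 ± 0.70 TPM and the laminin receptor gene BCAM from 67.1 ± 1.55 to 101 ± 8.28 TPM. KRT14, the basal keratin, fell from 10665 ± 149 to 7802 ± 602 TPM, and CAV1, of caveolae, fell from 432 ± 77.0 to 246 ± 19.96 TPM. Wound-activated genes had 9 rises, 6 falls and 6 that did not pass among 21 tested, the same adjusted over the list alone (camera adjusted p = 0.158). Fibronectin (FN1) rose from 80.4 ± 9.82 to 317 ± 6.94 TPM. FOSL1, an AP-1 subunit, fell from 61.3 ± 9.19 to 16.3 ± 1.56 TPM and the metalloproteinase gene MMP10 from 3.95 ± 0.52 to 0.71 ± 0.12 TPM. With median-of-ratios scaling the basal list had 4 rises and 8 falls and the wound list 5 rises and 10 falls.

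Of 8 G2/M (mitotic) genes tested, 5 fell, 0 rose and 3 did not pass, the same adjusted over the list alone. With no low-value filter 8 fell and 0 rose of the 22 tested, so most did not pass. At an unadjusted p below 0.05 limma also gave 0 rises for the differentiation, G2/M, ribosome biogenesis and ribosomal protein lists. CCNB1, the mitotic cyclin, fell from 5.90 ± 1.48 to 1.23 ± 0.40 TPM, UBE2C from 3.76 ± 0.80 to 0.54 ± 0.28 TPM and CDC20, an activator of the anaphase-promoting complex, from 3.08 ± 0.66 to 0.53 ± 0.25 TPM. ANLN, of the contractile ring, fell from 12.9 ± 2.23 to 7.02 ± 2.22 TPM. The proliferation marker MKI67 was under the filter, at 0.55 ± 0.14 and 0.09 ± 0.03 TPM, and was not tested. Camera gave down with adjusted p = 7.28e-04 (adjusted p = 0.394 with an estimated correlation). Among 16 S-phase genes 6 rose, 0 fell and 10 did not pass, and 5 rose adjusted over the list alone; 1 fell at an unadjusted p below 0.05 (camera adjusted p = 0.943; fry up, adjusted p = 0.004). CLSPN, of the replication checkpoint, rose from 2.10 ± 0.20 to 11.1 ± 0.82 TPM and GMNN, an inhibitor of origin licensing, from 4.70 ± 1.38 to 15.1 ± 1.97 TPM. CDT1, of origin licensing, rose by 0.60 (adjusted p = 0.0468), which did not pass without DMSO replicate 1 (adjusted p = 0.123), DMSO replicate 3 (0.133) or PY-60 replicate 3 (0.08), nor with median-of-ratios (0.146, log2 fold change 0.42) or upper quartile scaling (0.143), no low-value filter (0.0962) or no mean-variance trend (0.0609). MCM2, of the replicative helicase, rose by 0.61, but its adjusted p was 0.0574 with median-of-ratios and 0.0561 with upper quartile scaling. With either scaling 2 S-phase genes rose and 5 fell, and 6 G2/M genes fell and 0 rose.

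Ribosome biogenesis genes had 13 falls, 0 rises and 4 that did not pass among 17 tested, the same adjusted over the list alone. NOP2, an rRNA methyltransferase gene, fell from 27.1 ± 1.85 to 11.2 ± 2.41 TPM, NOP56 from 87.7 ± 11.4 to 47.5 ± 3.73 TPM, PES1 from 44.6 ± 5.25 to 25.3 ± 1.67 TPM and RRS1 from 14.8 ± 0.77 to 7.17 ± 1.29 TPM. Camera gave down with adjusted p = 2.60e-06 (adjusted p = 0.394 with an estimated correlation). Ribosomal protein genes showed 1 fall, 0 rises and 28 that did not pass among 29 tested by limma, and 0 passed adjusted over the list alone. At an unadjusted p below 0.05 limma gave 1 fall. That fall, of RPL27 (969 ± 4.91 to 850 ± 81.4 TPM), did not pass when any library other than PY-60 replicate 2 was left out (adjusted p between 0.0538 and 0.166), nor with a replicate block (0.0569), no low-value filter (0.0662) or no mean-variance trend (0.134). The list's median was 0.003 and its mean -0.005. That median lay at percentile 91.42 of random lists matched on mean expression, opposite to the camera direction. Down in camera means lower than the other genes and not below 0, and the median of all genes was 0.27. Camera gave down with adjusted p = 0.049 (adjusted p = 0.861 with an estimated correlation), and 0.301 without DMSO replicate 1, 0.131 without PY-60 replicate 1, 0.0707 without PY-60 replicate 3, 0.0716 rescaled to the total of the rows held and 0.0534 with a pseudocount of 0.1. With median-of-ratios scaling 28 of them fell, since that scaling lowered every gene by a similar amount.

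Most mesenchymal and matrix genes rose, with 13 rises, 1 fall and 3 that did not pass among 17 tested, the same adjusted over the list alone. N-cadherin (CDH2) went from 0.25 ± 0.10 to 9.51 ± 0.60 TPM, biglycan (BGN) from 0.50 ± 0.23 to 11.4 ± 0.52 TPM, galectin-1 (LGALS1) from 30.7 ± 6.05 to 195 ± 9.92 TPM and the transcription factor gene TWIST1 from 1.23 ± 0.34 to 9.63 ± 0.90 TPM. Camera gave up with adjusted p = 0.0274 (adjusted p = 0.555 with an estimated correlation, and 0.0947 with a mean of at least 5 TPM), and with median-of-ratios scaling 12 rose and 3 fell. Markers of other cell types moved with them. Of 6 fibroblast markers 5 rose and 1 did not pass (camera up, adjusted p = 0.0405; adjusted p = 0.394 with an estimated correlation), among them decorin (DCN, 2.30 ± 0.04 to 42.0 ± 2.55 TPM), PDGFRA (0.69 ± 0.03 to 5.84 ± 0.65 TPM) and THY1. The fibroblast list's camera adjusted p was 0.0639 without DMSO replicate 1, 0.0721 without PY-60 replicate 2, 0.063 without PY-60 replicate 3 and 0.111 with a mean of at least 5 TPM.

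Of 5 endothelial markers 4 rose and 1 did not pass (camera adjusted p = 0.0964, but 0.0188 with median-of-ratios scaling, 0.0192 with upper quartile scaling, 0.0475 with no low-value filter, 0.0433 with at least 1 TPM in 3 libraries and 0.0441 without PY-60 replicate 1), led by ESAM (0.13 ± 0.08 to 10.1 ± 0.07 TPM). All 5 immune markers tested rose (camera adjusted p = 0.0992), led by CD4 (0.20 ± 0.08 to 4.73 ± 0.43 TPM) and CD74 (3.32 ± 0.40 to 8.49 ± 1.90 TPM). Of 9 melanocyte markers 3 rose and 6 did not pass (camera adjusted p = 0.728), and the rise of MITF (9.87 ± 1.2 to 15.1 ± 1.88 TPM) did not pass with median-of-ratios (adjusted p = 0.083) or upper quartile scaling (0.0815). Of 6 sweat gland and simple epithelial markers 2 rose, 1 fell and 3 did not pass (camera adjusted p = 0.646). KRT19 rose from 192 ± 9.92 to 337 ± 14 TPM and KRT18 fell from 183 ± 9.02 to 85.9 ± 3.28 TPM. Counts for these 5 marker lists were the same adjusted over the list alone. Rises were common among low-expressed genes in general, with 1816 among 2926 genes of 1 to 5 TPM. Against random lists matched on mean expression, the list median lay at percentile 86.15 for immune and 90.79 for endothelial markers. It lay at 99.9 for fibroblast, 68.63 for sweat gland and 16.03 for melanocyte markers. The filter on the mean of all libraries admits genes such as CD4 through their PY-60 level. Without that filter 6 of 10 immune, 5 of 8 endothelial, 5 of 8 fibroblast and 3 of 11 melanocyte markers rose and 0 fell. Of 8 sweat gland and simple epithelial markers 3 then rose and 1 fell. With median-of-ratios scaling rises and falls were 5 and 1 for fibroblast, 4 and 0 for endothelial, 4 and 0 for immune, 2 and 3 for melanocyte and 2 and 3 for sweat gland markers, and the melanocyte median was -0.16.

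Type I interferon response genes rose, with 24 rises, 1 fall and 3 that did not pass among 28 tested, and 26 rises and 1 fall adjusted over the list alone. IFIT1 rose from 2.46 ± 0.84 to 17.4 ± 3.01 TPM, RSAD2 (viperin) from 3.15 ± 0.75 to 20.4 ± 3.44 TPM, and OAS1, a double-stranded RNA sensor, from 6.74 ± 0.69 to 31.8 ± 4.78 TPM. Camera gave up with adjusted p = 4.73e-04 (adjusted p = 0.394 with an estimated correlation). With median-of-ratios scaling 19 rose and 1 fell. Of 16 inflammatory cytokine and chemokine genes 8 rose, 3 fell and 5 did not pass, and 9 rose adjusted over the list alone (camera adjusted p = 0.822). The chemokine gene CXCL6 went from 0.30 ± 0.26 to 11.4 ± 0.87 TPM, ICAM1 from 4.48 ± 0.74 to 17.3 ± 1.00 TPM and TNF from 0.35 ± 0.18 to 3.45 ± 0.27 TPM, opposite to IL1A. With median-of-ratios scaling 8 of these rose and 4 fell.

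**Figure D3:**
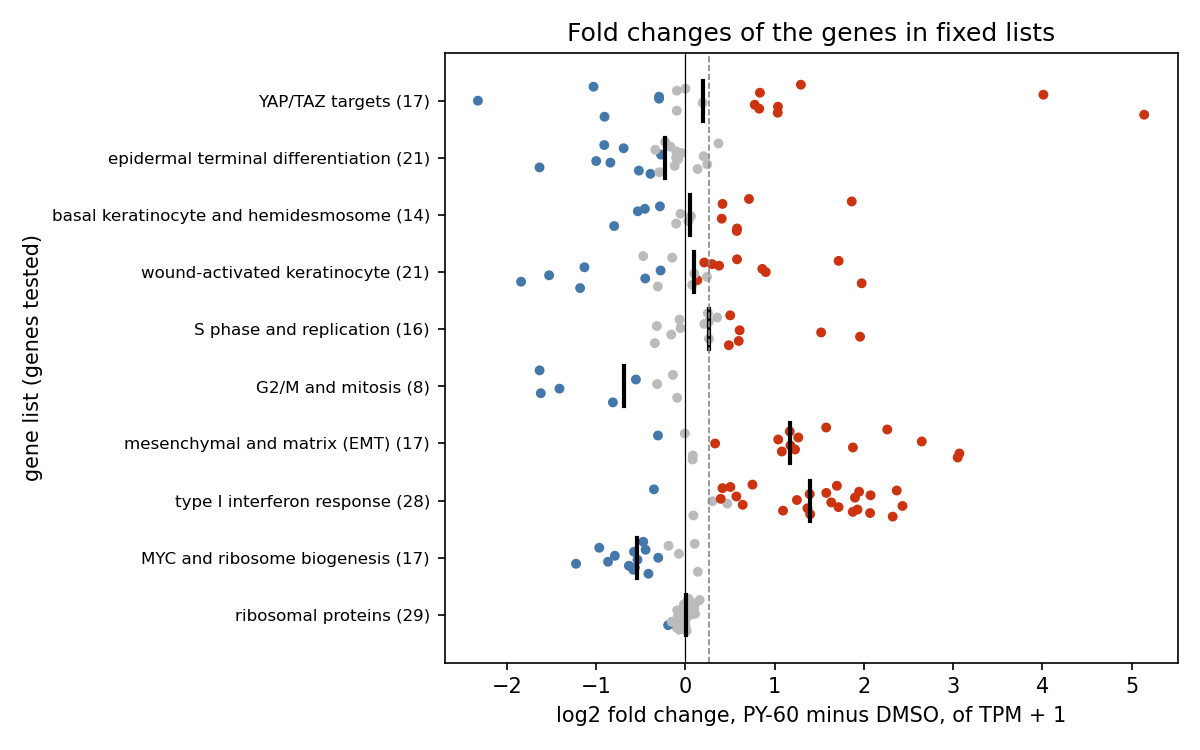
Log2 fold change of TPM + 1 (x axis, PY-60 minus DMSO) of each tested gene in 10 fixed lists (y axis, number tested in parentheses); red genes rose, blue fell, grey did not pass, black bars are list medians and the dashed line is the median of all genes, 0.27. Ribosome biogenesis genes had 13 falls and 0 rises, interferon genes 24 rises and 1 fall, and with median-of-ratios scaling these counts were 15 and 0, and 19 and 1.

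Immediate early and AP-1 genes split, with 6 rises, 6 falls and 7 that did not pass among 19 tested, the same adjusted over the list alone. FOS rose from 23.9 ± 1.50 to 112 ± 6.83 TPM and IER3 fell from 211 ± 7.53 to 67.6 ± 9.08 TPM. Camera gave down with adjusted p = 0.0405 (adjusted p = 0.394 with an estimated correlation), and this did not pass without DMSO replicate 3 (adjusted p = 0.0832) or PY-60 replicate 3 (0.063), or with a mean of at least 5 TPM (0.242). Actin cytoskeleton and SRF genes had 5 rises, 6 falls and 4 that did not pass among 15, with 7 falls adjusted over the list alone (camera down, adjusted p = 0.0814, or 0.0475 with no low-value filter; median -0.15, mean 0.16). CNN1 and CNN3, which encode calponins, rose from 0.83 ± 0.57 to 8.11 ± 0.98 TPM and from 41.3 ± 7.72 to 82.3 ± 3.77 TPM, and the actin regulator gene CORO1C fell from 132 ± 19.3 to 90.3 ± 4.07 TPM. Of 11 Notch genes 7 rose, 2 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.688). LFNG rose from 7.12 ± 1.73 to 31.8 ± 1.78 TPM, HEY1 from 0.64 ± 0.33 to 4.33 ± 0.81 TPM and HES5 fell from 13.3 ± 1.73 to 4.17 ± 0.58 TPM. With median-of-ratios scaling the immediate early list had 3 rises and 11 falls, the actin list 3 and 9, and the Notch list 5 and 4.

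Stress and metabolic lists contained large single changes, and no such list passed camera (adjusted p between 0.158 and 0.785). Against random lists matched on mean expression, the medians of some of them stood high. The percentile was 99.31 for NRF2, 99.28 for the aryl hydrocarbon receptor, 97.81 for ATF4 and 97.5 for p53. It was 93.26 for cholesterol synthesis and 54.45 for hypoxia. Camera, without passing, gave the direction down for the p53, cholesterol and hypoxia lists and up for the others. The random lists drew each gene independently, so correlation between the genes of a list was not taken into account in these percentiles. Counts of these lists were the same adjusted over the list alone. ATF4 and unfolded protein response genes had 11 rises, 2 falls and 6 that did not pass, among the rises STC2 (0.96 ± 0.43 to 6.53 ± 1.88 TPM), CHAC1 (4.18 ± 1.01 to 16.4 ± 2.39 TPM) and the serine synthesis gene PSAT1 (38.1 ± 3.85 to 99.6 ± 1.85 TPM). NRF2 genes had 8 rises, 1 fall and 5 that did not pass, among them NQO1, a quinone reductase gene (32.6 ± 3.02 to 71.9 ± 4.59 TPM), and PIR (6.25 ± 0.44 to 19.4 ± 3.20 TPM). Aryl hydrocarbon receptor targets had 7 rises, 1 fall and 3 that did not pass, with CYP2S1 (13.1 ± 2.52 to 48.5 ± 4.45 TPM) and the receptor's repressor gene AHRR (0.32 ± 0.06 to 2.41 ± 0.18 TPM) rising. The p53 list had 9 rises, 6 falls and 4 that did not pass. DDB2, of DNA repair, rose from 11.9 ± 0.88 to 27.3 ± 2.56 TPM, and SFN (14-3-3 sigma), an abundant epidermal protein, fell from 5077 ± 276 to 2120 ± 99.1 TPM. Hypoxia and glycolysis genes had 7 rises, 7 falls and 7 that did not pass. CA9 rose from 1.14 ± 0.31 to 8.40 ± 1.38 TPM and ENO2 from 2.78 ± 0.87 to 49.6 ± 2.33 TPM, while the glucose transporter gene SLC2A1 fell from 350 ± 32.5 to 128 ± 5.98 TPM. Cholesterol synthesis genes had 6 rises, 4 falls and 8 that did not pass, with STARD4 rising from 18.5 ± 4.0 to 30.4 ± 4.24 TPM. The excess of rises in several of these lists depended on the scaling. With median-of-ratios scaling rises and falls were 7 and 6 for ATF4, 6 and 6 for NRF2, 7 and 2 for the aryl hydrocarbon receptor, 4 and 9 for p53 and 7 and 11 for hypoxia. The cholesterol list then had 1 rise and 11 falls and passed camera as down (adjusted p = 0.0156, and 0.0158 with upper quartile scaling).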

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

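Tests with a pseudocount of 0.1, a mean of at least 5 TPM, protein-coding genes or no mean-variance trend were chosen after seeing the data; the others were planned. The planned count tests (the DESeq2 Wald test, limma-voom) were not run because the values are TPM, and the planned count scalings and filters were applied to TPM. Median-of-ratios and upper quartile scaling raised the falls from 1513 to 3434 and 3399, and the at least 2-fold falls from 114 to 367 and 361; all 114 were shared, and the scalings' own shift of every gene by a similar amount accounts for this. A mean of at least 5 TPM, which tests fewer genes, gave 2831 rises and 1037 at least 2-fold rises. Under all other settings run, these counts stayed within 1.5 times of the main values; leaving out each library gave 4082 to 5076 rises, 1264 to 1577 falls, 2120 to 2445 at least 2-fold rises and 111 to 136 at least 2-fold falls.

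With an estimated correlation the differentiation and G2/M lists no longer passed (adjusted p = 0.394 for both). With fry, which does not compare a list with other genes, the YAP/TAZ list (adjusted p = 0.00281) and the S-phase list (0.00400) passed as up. So did 9 other lists that did not pass camera: Hippo, basal, inflammatory, ATF4, NRF2, aryl hydrocarbon receptor, Notch, immune and endothelial (adjusted p between 7.49e-06 and 0.0209). The immediate early (0.112) and ribosomal protein (0.977) lists no longer passed with fry. With a mean of at least 5 TPM the mesenchymal (0.0947), fibroblast (0.111), immediate early (0.242) and ribosomal protein (0.283) lists no longer passed camera. No list that passed and no called named gene turned its direction under the settings run. Of 1995 refits of called named genes 1970 still passed, and 25, in 7 genes (CDT1, HSD17B7, MCM2, MITF, RPL27, ANXA2 and FJX1), did not. 

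With a replicate block the counts were 4590 rises and 1468 falls. The correlations of same-numbered deviations were 0.057, 0.013 and 0.014, so the numbers were not taken to pair libraries. Among the 10 splits of the libraries into 3 and 3, only 1, the real one, gave 4671 rises, 1513 falls, 2252 at least 2-fold rises or 114 at least 2-fold falls. No other split gave more than 1 called gene, counting both directions. With 10 splits there are too few for a share under 0.05. Depth limits cannot be set from TPM.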

Other observations

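All tests of explanations here except the ratio of olfactory receptor sums and the test of the histone deacetylase inhibitor list were chosen after the result they concern was seen. Of 19 neuronal genes tested in a list written before their values were seen, 18 rose and 1, MAP2, did not pass, with a median log2 fold change of 2.35. The microtubule-associated tau gene MAPT went from 1.12 to 24.7 TPM, the neurofilament gene NEFM from 1.40 to 26.7 TPM, the kinesin gene KIF5C from 0.03 to 15.7 TPM and the collapsin response gene DPYSL3 from 0.59 to 15.8 TPM. With median-of-ratios scaling 17 rose and 1 fell. The filter on the mean of all libraries admits genes such as KIF5C through their PY-60 level, so the list was also counted with no low-value filter, where 25 of 27 rose and 0 fell. Of germline and cancer-testis genes 21 were in the table and 0 reached the filter; with no low-value filter 18 were tested, 2 rose and 0 fell.

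Rises were concentrated among genes of low expression. The median log2 ratio was 0.93 for 3134 genes of 0.1 to 1 TPM, which were not tested, 1.09 for 2926 genes of 1 to 5 TPM, 0.37 for 3546 of 5 to 20 TPM, 0.04 for 2782 of 20 to 100 TPM and -0.11 for 820 of at least 100 TPM. Deeper PY-60 libraries would make a read worth more TPM with DMSO, but the DMSO to PY-60 ratio of that worth was 0.962 over 9 library pairs, and the closed sum of TPM would move all classes alike, but the classes of 1 to 5 and 20 to 100 TPM differed by 1.06. Olfactory receptor genes summed to 2.59 times as much TPM with PY-60, as genomic DNA could give, but their mean gain was 0.0134 of the median gain of genes of 1 to 5 TPM, too small for genomic DNA to be the whole cause. A candidate explanation is a response like that to histone deacetylase inhibitors, which would release silent genes. Of 20 such response genes tested 14 rose, 3 fell and 3 did not pass, and with median-of-ratios scaling 13 rose and 6 fell. CRIP1, SYT11, DHRS2 and CLU (128 to 618 TPM) rose and H1F0 rose from 138 to 254 TPM, although HIST1H2AC and HIST1H2BJ fell. CLU and H1F0 were not silent with DMSO. The list median lay at percentile 100 of random lists matched on the mean of all libraries. Such matching sets genes raised from near 0 against genes of middle level. The neuronal list lay at percentile 100 too, so the test is not specific. Of 18 germline and cancer-testis genes tested with no low-value filter 2 rose (median log2 fold change 0.03). The log2(TPM + 1) scale compresses changes near 0, so this cannot exclude a release at such levels. None of these genes reached a mean of 1 TPM over the 6 libraries, so a release to that mean was not seen.

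The rises of DCN and THY1 could come from fibroblasts in the PY-60 cultures or from the keratinocytes themselves. The median PY-60 level of the 9 other abundant fibroblast transcripts measured was 0.313 of that of DCN, high enough for fibroblasts, with TIMP3 at 87 TPM, MMP2 at 37.9 TPM and FBN1 at 4.46 TPM. TIMP3 and CCDC80 were also present with DMSO (24.6 and 37.2 TPM), COL6A3 was 0.17 TPM with PY-60, MFAP5 was 523 and 505 TPM, and 0 of the 3 genes of type I and III collagen were measured. These sources cannot be told apart while those collagens, the most abundant fibroblast transcripts, are not analysed here.

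Tubulin genes moved apart. Of 8 alpha- and beta-tubulin genes of at least 20 TPM, 6 fell and 2, TUBA1A (245 to 361 TPM) and TUBB3 (107 to 207 TPM), rose, with the same counts under median-of-ratios scaling. Reads moved among the 9 measured paralogs would leave their sum in place, but it went from 4292 ± 37.3 to 1909 ± 41.6 TPM (SD, n = 3), a ratio of 0.445. Reads moved to other paralogs cannot be told apart from a fall of the messages, since 3 of the 12 genes of the list were not analysed here. Tubulin autoregulation, a loss of message that follows excess free tubulin, might lower every member, but 2 rose. TPM does not separate loss of message from new transcription, so these 2 rises cannot decide the question. For the 6 that fell autoregulation was not tested.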
